A study of Mus musculus with 105 samples.

How the data were processed

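RNA was measured on Illumina mouse bead arrays in epithelium and mesenchyme of the mandible at the first lower molar site. The 105 arrays came as 6 tables. They covered laser-captured tissue at E11.5 and E12.0 (12 arrays), at E12.5, E13.0 and E13.5 (18) and labelled EK at E14.5 (3), tissue hand-dissected after dispase at E10, E11 and E13 (12), cultured E10 mesenchyme and E13 epithelium (36), and laser-captured tissue of Msx1 null, Pax9 null and wildtype embryos (24). The wildtype series used CD-1 mice and the Msx1 and Pax9 samples C57BL6. Cultures had Bmp4, Fgf8, Shh or i-Gsk3b, no treatment (isolated), or were labelled intact culture. Groups were taken from the sample labels, and tissue from title and source, since some mesenchyme samples have a description that says epithelium. In the cultured table the columns headed Nude were assigned to isolated by elimination, and in the Msx1 and Pax9 table those headed P Lac to Pax9 null.

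Per the file headers, the deposited tables hold an average signal as intensity for each of 45281 probes and a detection p-value against the negative control probes. The signals had no normalization between arrays. They had background subtracted in 5 tables, whose lowest values lay below 0, and not in the Msx1 and Pax9 table, whose lowest signal was 35.19. The authors also deposited 1 log2 value per probe and array, normalized by the authors with lumi per the submitters' notes. That it is log2 was read from its range and its slope against the signal, since its exact transform is not stated. These values served only as an alternative. Other columns per sample (spread and number of beads) were not used.

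Each table was processed on its own, since the tables may differ in batch, with R 4.3.3 and limma 3.58.1. Background was corrected with neqc, with negative control levels inferred from the detection p-values, an offset of 16 and quantile normalization. A probe was kept when its detection p-value was under 0.01 in at least as many arrays as the smallest group of its table, 3 or, hand-dissected, 2. Of several probes of a gene the one with the highest mean over the table stood for it. Of the probe symbols 12013 were updated, and 34854 probes have a symbol in the RefSeq table used. This left 11850, 12887, 8301, 13509, 14410 and 13081 genes in the 6 tables, in the order above. Between 24.8% and 39.4% of probes were detected per array, so genes near background are missed or have compressed differences. Where a named gene was detected in at most 1 of 3 arrays of 1 group (0 of 2, hand-dissected), its difference is a fold against the background level, written as at least.

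One linear model per table, with a mean per group and moderated variances, gave each difference. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Differences between effects (stage change or null effect by tissue, treatment effect by tissue, Pax9 null against Msx1 null) were tested as interaction contrasts. Shared calls counted genes called in the same direction in 2 comparisons. Expected counts are products of the shares called. They take no account of isolated arrays that Bmp4 and i-Gsk3b share, for which 100 simulations without effects, and 100 with the called differences placed on random genes, gave what sharing makes. Replicate numbers do not tie samples to an animal or litter, so no pairing was used. Chip and scan batches are not given.

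For genes named in the text a rule was fixed before the data were examined. It took (1) the perturbed gene, (2) up to 8 genes per direction with the largest difference among called genes whose groups do not overlap and which have a real symbol, (3) up to 6 members of each gene list by adjusted p, and (4) a list of core genes of tooth signalling. Also fixed then were the comparisons, the alternatives, except where the closing section says otherwise, and 23 gene lists with 483 members, 8 of them missing from the array. Lists cover tissue markers and regulators, pathway targets, stress and metabolic programs and other cell types. Each was tested in 28 comparisons of 2 groups with camera at a preset correlation of 0.01, and also with an estimated correlation, adjusted over all 644 tests. Members were also adjusted over the list alone.

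The pipeline was tested on simulated data with genes changed by known amounts in these designs. A log2 change of 1 was recovered for 88% of genes between laser-captured tissues at E11.5, for 100% between hand-dissected tissues at E10 and for 60% in the laser-captured tissue difference of E13.5 minus E12.5. At a log2 change of 0.5 these shares were 28%, 68% and 6%. Alternatives changed 1 choice each: median scaling in place of quantiles, no background correction, no detection filter, every probe in place of 1 per gene, only the groups compared in the model, replicate number as a block, the authors' values, each replicate number left out, each array left out, the mean of the other 3 treatments as control, and the estimated correlation. Up to 100 other splits of the samples were counted for each comparison with 3 arrays per group. The EK samples have no comparison group and are described by level alone. Comparisons across tables were left out because table and tissue source go together.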

Results

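The series measured RNA in mouse tooth germs with Illumina bead arrays, to follow the exchange between dental epithelium and mesenchyme in time, in mutants and after signalling treatments. There were 105 arrays in 37 groups: 12 of laser-captured (LCM) epithelium and mesenchyme at E11.5 and E12.0, 18 at E12.5, E13.0 and E13.5, 3 labelled EK at E14.5, 12 of hand-dissected tissue at E10, E11 and E13, 36 of cultured E10 mesenchyme or E13 epithelium, and 24 of epithelium and mesenchyme from Msx1 null, Pax9 null and wildtype embryos. Groups held 3 arrays, or 2 in the hand-dissected tissue, and the number of arrays limits the precision of every value. Between 24.8% and 39.4% of the 45281 probes were detected per array. A value with ± is a log2 difference with its standard error, and n is 3 against 3 arrays, or 2 against 2 in hand-dissected tissue, unless another n is given. Where a gene was detected in at most 1 of the 3 arrays of 1 group, or in 0 of 2, its difference is given as a fold that it reached at least, and its differences between effects are left out. Unless stated, every array of 1 group lay above every array of the other for each gene named as different, which 10% of unchanged genes do by chance with 3 against 3 arrays. With 2 against 2 arrays more unchanged genes do so. In the hand-dissected comparisons 69.3% to 83.7% of all genes did not overlap, so this adds little there. After a gene list, the first counts are over all genes tested, and the adjusted p of the set test is given for a preset and then for an estimated correlation. Because replicate numbers do not tie samples to animals, p-values measure the spread between these samples.

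Which genes separate the tooth epithelium from the mesenchyme under it, and does that hold from stage to stage? In laser-captured tissue the adhesion gene Cdh1 was higher in epithelium at E11.5 (4.58 ± 0.21, adjusted p = 1.9e-08) and at E12.0 (4.79 ± 0.21, adjusted p = 1.4e-08), as was the signalling ligand Shh at E12.0 (at least 22.7-fold higher, adjusted p = 6.8e-09). Epithelial Edar, the receptor for ectodysplasin, was at least 7.67-fold higher at E11.5 and 3.98 ± 0.24 at E13.5, and Wnt10b was at least 4.73-fold higher at E13.5. In mesenchyme, collagen Col3a1 (-3.97 ± 0.17), the proteoglycan Lum (at least 12.8-fold lower) and the homeobox gene Msx1 (-3.12 ± 0.19, adjusted p = 2.1e-07) were higher at E11.5, so their epithelium minus mesenchyme differences were negative. Msx1 stayed lower in epithelium at E13.5 (-3.43 ± 0.12, adjusted p = 3.4e-12), as did Lhx8 (-2.56 ± 0.15), Inhba (-3.54 ± 0.24) and Pax9 (at least 4-fold lower), while Bmp4 was -0.99 ± 0.32 at E11.5 and, in a table of its own, -3.50 ± 0.18 at E13.5. At E11.5, epithelial markers had 30 of 30 measured members higher and 0 lower (30 and 0 over the list alone, set test adjusted p = 7.6e-31 and 0.0036). Mesenchymal markers had 2 of 24 measured members higher and 19 lower (3 and 19 over the list alone, set test adjusted p = 3.0e-09 and 0.0029). Dental epithelium regulators had 16 of 21 measured members higher and 1 lower (17 and 1 over the list alone, set test adjusted p = 7.1e-10 and 0.0011) at E13.5. At that stage dental mesenchyme regulators had 0 of 20 measured members higher and 17 lower (0 and 17 over the list alone, set test adjusted p = 3.8e-15 and 0.0012). Markers of other cells also parted the tissues: endothelial markers had 0 of 13 measured members higher and 12 lower (1 and 12 over the list alone, set test adjusted p = 1.1e-08 and 0.0045) and blood cell markers 0 of 9 measured members higher and 8 lower (0 and 8 over the list alone, set test adjusted p = 1.0e-07 and 0.079) at E13.5. Hypoxia and glycolysis genes had 17 of 24 measured members higher and 1 lower (20 and 1 over the list alone, set test adjusted p = 1.0e-06 and 0.062) at E12.5.

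By limma, the laser-captured tissues differed in 3588 of 11850 genes, 1697 higher and 1891 lower in epithelium, at E11.5, and in 3532 of 11850 genes, 1861 higher and 1671 lower at E12.0. At E12.5 the count was 3992 of 12887 genes, 1926 higher and 2066 lower, at E13.0 5241 of 12887 genes, 2635 higher and 2606 lower and at E13.5 4554 of 12887 genes, 2325 higher and 2229 lower. At E11.5 the count was 1007 with median scaling, 588 higher and 419 lower. At E12.0 it was 1463 with median scaling, 1076 higher and 387 lower, where the median of all genes moved by 0.23, and at E13.0 5123 with median scaling, 3727 higher and 1396 lower, where the median of all genes moved by 0.20.

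**Figure D1:**
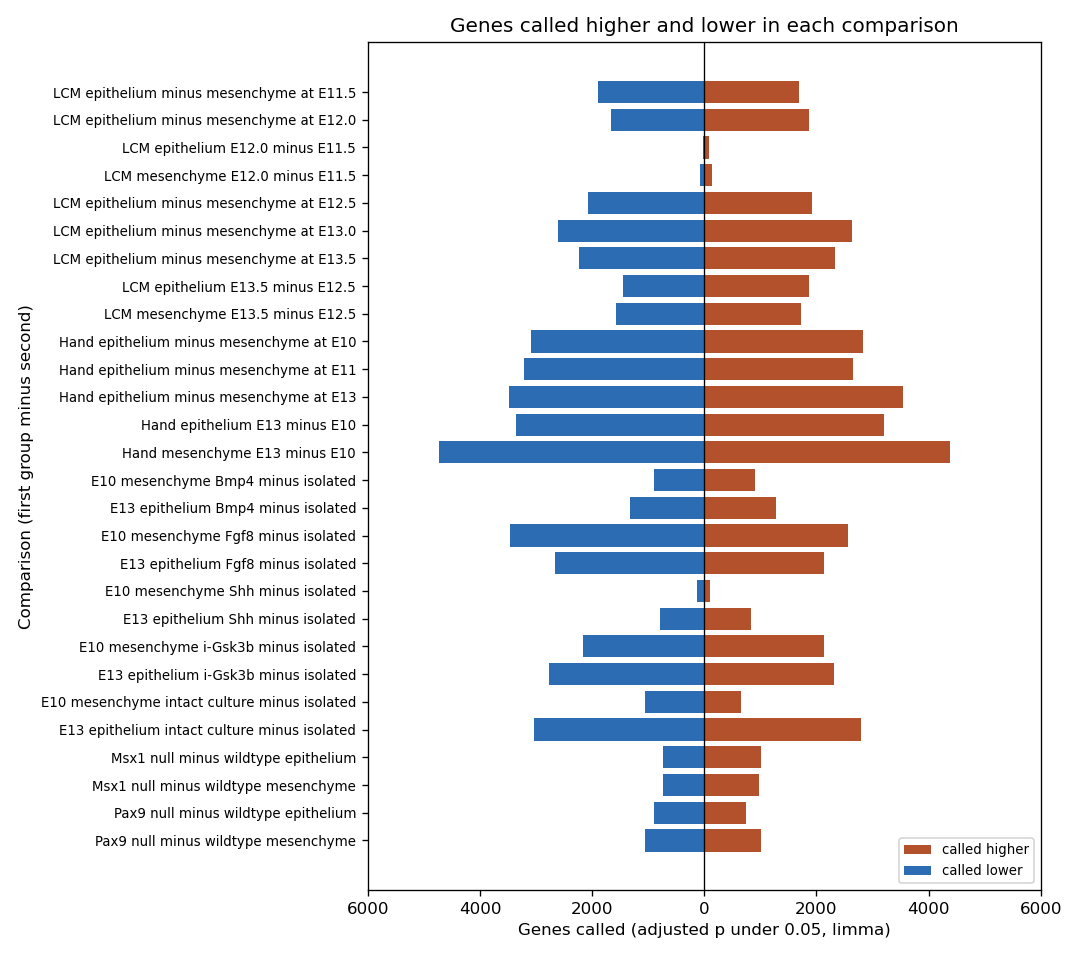
Number of genes called higher (bars to the right of 0) and lower (bars to the left) in each comparison of 2 groups, at an adjusted p under 0.05 by limma. The smallest totals of both bars belong to the laser-captured stages E12.0 minus E11.5, with 100 genes in epithelium and 210 in mesenchyme.

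Few genes changed between E11.5 and E12.0 by the test. In epithelium the calcium channel gene Ryr2 rose (3.21 ± 0.51, adjusted p = 0.018), with Sostdc1 (1.02 ± 0.20), a secreted antagonist of Wnt and Bmp signals, the Hedgehog receptor gene Ptch1 (0.67 ± 0.10) and Tbx1 (0.92 ± 0.17), while the tight junction gene Cldn4 (-2.37 ± 0.30, adjusted p = 0.0063) and Fgf10 (-0.96 ± 0.19) fell. In mesenchyme Ryr2 (at least 9.49-fold higher, adjusted p = 0.0049), the Wnt response factor Lef1 (1.17 ± 0.19), Sostdc1 (1.12 ± 0.20) and Tnc (1.02 ± 0.15) rose, while Cd40 (at least 1.37-fold lower) and Col9a1 (-0.85 ± 0.13) fell. The core genes had 3 of 32 measured members higher and 0 lower (6 and 0 over the list alone, set test adjusted p = 0.018 and 0.27) in mesenchyme, and 2 of 32 measured members higher and 1 lower (6 and 2 over the list alone, set test adjusted p = 0.027 and 0.29) in epithelium. The test called 100 of 11850 genes, 78 higher and 22 lower in epithelium, and 210 of 11850 genes, 140 higher and 70 lower in mesenchyme. With median scaling the counts were 16 (15 higher and 1 lower, with the median of all genes moved by 0.43) and 10 (10 higher and 0 lower, moved by 0.12), and with only the groups compared 3 and 105. The stage change differed between the tissues for 1 gene, Myl4 (adjusted p = 0.032, n = 3 in each of 4 groups, 3 of them at background), against 738 genes at an unadjusted p under 0.05. Single arrays moved these counts: the epithelial count was 27 and 288 without E11.5 epithelium 2 or 3, and 44, 33 and 15 without E12.0 epithelium 1, 2 or 3. The mesenchymal count was 94, 32 and 84 without E11.5 mesenchyme 1, 2 or 3, and 58, 76 and 64 without E12.0 mesenchyme 1, 2 or 3. The difference between tissues called 20 genes without E11.5 epithelium 1, 3 without E12.0 epithelium 3, 2 without E12.0 mesenchyme 1, 1 without E11.5 epithelium 3 or E12.0 mesenchyme 2, and 0 by limma without each of the other arrays.

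Genes of keratinocyte differentiation rose in the epithelium from E12.5 to E13.5. Dmkn (3.48 ± 0.19, adjusted p = 8.6e-09), Krtdap (2.11 ± 0.14) and the desmosomal cadherin Dsg1a (at least 6.03-fold higher) rose, with keratins Krt15 (at least 6.09-fold higher) and Krt5 (1.90 ± 0.28) and the enamel organ gene Odam (at least 4.46-fold higher). Keratinocyte differentiation genes had 6 of 10 measured members higher and 0 lower (7 and 0 over the list alone, set test adjusted p = 6.9e-06 and 0.014). Shh (-2.34 ± 0.37, adjusted p = 4.1e-04), the Wnt antagonist Dkk4 (at least 2.44-fold lower), Lmo2 (-2.48 ± 0.34), Fgf20 (-1.46 ± 0.37) and the Ets factors Etv5 (-2.03 ± 0.32) and Etv1 (-1.86 ± 0.34) fell, while Wnt10a (1.18 ± 0.16) and Wnt7b (1.06 ± 0.16) rose. Fgf pathway targets had 3 of 22 measured members higher and 9 lower (5 and 10 over the list alone, set test adjusted p = 0.035 and 0.45). The test called 3327 of 12887 genes, 1871 higher and 1456 lower. The count was 3225 with median scaling, 2621 higher and 604 lower, where the median of all genes moved by 0.15. Without E13.5 epithelium 1 it was 2187.

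In mesenchyme over the same stages, the neuropeptide gene Calca (3.96 ± 0.30, adjusted p = 4.6e-07), the Bmp family member Gdf10 (3.57 ± 0.40), the protease gene Fap (3.04 ± 0.33) and the early response factors Egr2 (at least 12.2-fold higher, adjusted p = 8.1e-05), Egr1 (3.01 ± 0.71) and Fos (at least 5.74-fold higher) rose. The cartilage factor Sox9 (-1.70 ± 0.24) and Col2a1 (at least 2.32-fold lower) fell. Wnt pathway targets had 11 of 21 measured members higher and 1 lower (13 and 1 over the list alone, set test adjusted p = 1.7e-04 and 0.18). Among the higher ones were Wif1 (at least 5.66-fold higher), Apcdd1 (2.03 ± 0.26) and Tcf7 (1.47 ± 0.16). Cell cycle genes fell, with 0 of 32 measured members higher and 18 lower (0 and 20 over the list alone, set test adjusted p = 1.1e-07 and 0.016). Epithelial markers moved too, with 13 of 29 measured members higher and 0 lower (13 and 0 over the list alone, set test adjusted p = 4.5e-06 and 0.084), such as Perp (2.10 ± 0.20) and Krt14 (1.35 ± 0.14), beside keratin Krt17 (2.65 ± 0.27). The test called 3302 of 12887 genes, 1727 higher and 1575 lower. Median scaling gave 2803, 2253 higher and 550 lower, and moved the median of all genes by 0.13. The stage change itself differed between the tissues for 481 of 12887 genes, 217 higher and 264 lower in epithelium (n = 3 in each of 4 groups), among them Sox9 (2.53 ± 0.34, adjusted p = 4.5e-04), Calca (-2.44 ± 0.43), Apcdd1 (-2.22 ± 0.37) and Krt17 (-1.47 ± 0.39). This count was 307 without E13.5 epithelium 1 and 303 without E13.5 mesenchyme 3.

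Hand-dissected tissue gave the same question a wider range of stages. Its 2 arrays per group correlated at 0.996 to 0.998, against at most 0.995 between arrays of a group in the other series. Whether these arrays are separate animals or repeated measurements of 1 pool is not known. The p-values of the hand-dissected comparisons may therefore not reflect spread between animals. Fgf8 was higher in epithelium at E10 (5.45 ± 0.10, adjusted p = 9.9e-12) and at least 72.8-fold higher at E11, with Shh at least 23.6-fold higher and Krt14 higher (5.58 ± 0.09) at E10. At E13 the mesenchymal factors Osr2 (-6.71 ± 0.10, adjusted p = 3.9e-13), Msx1 (-6.62 ± 0.12, adjusted p = 1.7e-12), Lhx8 (-5.56 ± 0.11) and the transcription factor Prrx1 (-6.03 ± 0.10) were lower in epithelium. Bmp4 was higher in epithelium at E10 (2.83 ± 0.11, adjusted p = 1.9e-09) and E11 (1.82 ± 0.11) and lower there at E13 (-5.29 ± 0.11, adjusted p = 4.2e-12). The p53 target Cdkn1a was higher in epithelium at E10 (4.18 ± 0.12). Hypoxia and glycolysis genes had 18 of 21 measured members higher and 1 lower (18 and 1 over the list alone, set test adjusted p = 1.8e-06 and 0.013) at E13. At the same stage muscle genes had 0 of 15 measured members higher and 14 lower (0 and 14 over the list alone, set test adjusted p = 1.3e-09 and 0.0089). The test called 5912 of 13509 genes, 2823 higher and 3089 lower in epithelium at E10, 5858 of 13509 genes, 2644 higher and 3214 lower at E11, and 7017 of 13509 genes, 3536 higher and 3481 lower at E13. At E10 the count was 5428 with median scaling, 4153 higher and 1275 lower, where the median of all genes moved by 0.17.

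In hand-dissected epithelium between E10 and E13, the hemidesmosome gene Col17a1 (at least 87.5-fold higher, adjusted p = 1.2e-11), keratins Krt5 (at least 78.9-fold higher) and Krt15 (4.71 ± 0.14), Edar (2.58 ± 0.11) and Wnt10a (2.95 ± 0.14) rose. Bmp4 (-4.69 ± 0.11, adjusted p = 3.9e-11), Msx1 (-3.81 ± 0.12), Fgf8 (-2.19 ± 0.10), Shh (-1.32 ± 0.10) and the early embryonic factor Sall4 (-6.46 ± 0.10) fell. Bmp pathway targets had 2 of 21 measured members higher and 12 lower (2 and 13 over the list alone, set test adjusted p = 1.1e-04 and 0.029). In mesenchyme Osr2 (7.48 ± 0.10, adjusted p = 7.4e-13), Dcn (6.80 ± 0.17), Bmp4 (3.43 ± 0.11, adjusted p = 2.9e-10) and Inhba (at least 25.8-fold higher) rose, while Sall4 (-6.17 ± 0.10), Msx2 (-4.24 ± 0.14) and the RNA-binding genes Lin28b (at least 26.3-fold lower) and Lin28a (at least 15.3-fold lower) fell. Mesenchymal markers had 23 of 27 measured members higher and 2 lower (23 and 2 over the list alone, set test adjusted p = 1.6e-09 and 0.012), muscle genes 14 of 15 measured members higher and 0 lower (14 and 0 over the list alone, set test adjusted p = 1.6e-09 and 0.0089) and macrophage genes 14 of 14 measured members higher and 0 lower (14 and 0 over the list alone, set test adjusted p = 1.0e-05 and 0.019). Limma called 6577 of 13509 genes, 3214 higher and 3363 lower in epithelium and 9109 of 13509 genes, 4375 higher and 4734 lower in mesenchyme. Median scaling gave, in mesenchyme, 8629, 5797 higher and 2832 lower, and moved the median of all genes by 0.22. The change differed between tissues for 6355 of 13509 genes, 3164 higher and 3191 lower in epithelium (n = 2 in each of 4 groups). Median scaling gave 5904, 1448 higher and 4456 lower, and moved the median of all genes by -0.24. Bmp4 (-8.12 ± 0.16, adjusted p = 8.0e-11), Osr2 (-8.41 ± 0.14) and Krt15 (6.11 ± 0.20) were among them.

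The cultured tissues address which genes respond to a signal: each was compared with tissue of the same kind labelled isolated. In E10 mesenchyme, Bmp4 lowered its own transcript (-1.55 ± 0.19, adjusted p = 2.2e-07). It raised Gata6 (4.56 ± 0.29, adjusted p = 3.0e-13), the heart factor Tbx20 (at least 16.1-fold higher), the secreted antagonists Dkk1 (4.22 ± 0.24) and Nog (3.98 ± 0.21, adjusted p = 1.2e-14), Smad6 (3.21 ± 0.17), Msx1 (2.60 ± 0.30) and Msx2 (2.59 ± 0.21). Bmp pathway targets had 20 of 23 measured members higher and 0 lower (20 and 1 over the list alone, set test adjusted p = 7.6e-31 and 8.7e-05). Barx1 (-3.36 ± 0.23, adjusted p = 2.9e-12), Fgf10 (-2.24 ± 0.17), Msc (at least 11.2-fold lower), Hic1 (at least 16.8-fold lower) and Lhx8 (-1.44 ± 0.26) fell, and Fgf pathway targets had 1 of 22 measured members higher and 10 lower (1 and 12 over the list alone, set test adjusted p = 4.7e-08 and 0.0046). Nerve and glia markers had 0 of 6 measured members higher and 3 lower (1 and 3 over the list alone, set test adjusted p = 0.031 and 0.083). Muscle genes had 0 of 15 measured members higher and 5 lower (0 and 6 over the list alone, set test adjusted p = 8.6e-05 and 0.42). The test called 1803 of 14410 genes, 898 higher and 905 lower. The count was 1455 with median scaling, 518 higher and 937 lower. It was 1159 without isolated mesenchyme 3 and 4887 against the mean of the other 3 treatments.

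Fgf8 in E10 mesenchyme raised the neuropeptide gene Tac1 (5.45 ± 0.32, adjusted p = 4.0e-14), the protease gene Mmp9 (4.46 ± 0.42), Tnc (3.87 ± 0.31) and the bone matrix gene Spp1 (3.79 ± 0.36), and the endogenous Fgf8 transcript was at least 1.81-fold lower. Fgf pathway targets had 17 of 22 measured members higher and 0 lower (18 and 0 over the list alone, set test adjusted p = 2.8e-09 and 0.0031), among them the phosphatase Dusp4 (2.46 ± 0.19, adjusted p = 2.0e-11), Etv4 (1.88 ± 0.20) and Ier3 (2.75 ± 0.22). The cell cycle inhibitor Cdkn1a (2.82 ± 0.19, adjusted p = 1.3e-12), Ccng1 (2.40 ± 0.19) and Phlda3 (2.41 ± 0.19) rose with p53 targets, which had 16 of 19 measured members higher and 1 lower (16 and 1 over the list alone, set test adjusted p = 9.2e-12 and 6.1e-04). Immediate early and heat shock genes had 21 of 22 measured members higher and 1 lower (21 and 1 over the list alone, set test adjusted p = 1.3e-09 and 0.12). Genes of the amino acid and unfolded protein response had 15 of 24 measured members higher and 1 lower (16 and 1 over the list alone, set test adjusted p = 7.5e-06 and 0.058). Gata3 (-2.16 ± 0.17, adjusted p = 4.1e-11), Id1 (-1.21 ± 0.15), Msx1 (-1.30 ± 0.30) and the macrophage receptor Cx3cr1 (-2.33 ± 0.16) fell. The test called 6032 of 14410 genes, 2564 higher and 3468 lower. Median scaling gave 6856, 966 higher and 5890 lower, and moved the median of all genes by -0.33.

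Shh in E10 mesenchyme raised the Hedgehog receptor and target Ptch1 (2.15 ± 0.19, adjusted p = 1.4e-08), Foxf1 (1.31 ± 0.20), Foxd1 (1.36 ± 0.26), Foxc2 (1.30 ± 0.15) and Pcp4l1 (2.30 ± 0.24). Hedgehog pathway targets had 10 of 16 measured members higher and 0 lower (12 and 0 over the list alone, set test adjusted p = 2.2e-23 and 1.7e-06). Gata3 (-2.07 ± 0.17, adjusted p = 2.5e-09), Msx1 (-1.81 ± 0.30), Msx2 (-1.51 ± 0.21), Id1 (-1.01 ± 0.15) and Krt14 (-2.55 ± 0.37) fell, and Bmp pathway targets had 0 of 23 measured members higher and 12 lower (1 and 15 over the list alone, set test adjusted p = 1.0e-18 and 7.9e-04). Fgf10 rose (0.78 ± 0.17). The endogenous Shh transcript did not pass the test. Limma called 230 of 14410 genes, 95 higher and 135 lower. Median scaling gave 327, 52 higher and 275 lower, and moved the median of all genes by -0.15. The count was 385 with only the groups compared and 3986 against the mean of the other 3 treatments. It was 140 and 111 without Shh mesenchyme 2 or 3, and 108 and 112 without isolated mesenchyme 1 or 2.

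In the same mesenchyme i-Gsk3b, read from its name as an inhibitor of the kinase Gsk3b, raised Sp5 (at least 103-fold higher, adjusted p = 1.1e-15), the Wnt deacylase Notum (at least 48.6-fold higher), Axin2 (4.24 ± 0.17, adjusted p = 6.4e-18), Nkd1 (4.57 ± 0.21), Apcdd1 (5.19 ± 0.18) and Lef1 (2.66 ± 0.21). Wnt pathway targets had 15 of 23 measured members higher and 1 lower (15 and 1 over the list alone, set test adjusted p = 2.4e-17 and 2.6e-04). The matrix genes Lum (4.95 ± 0.46) and Dcn (4.63 ± 0.28) also rose, as did Msx1 (1.98 ± 0.30) and Msx2 (1.89 ± 0.21). Ebf2 (at least 15.5-fold lower, adjusted p = 1.9e-15), the chemokine Cxcl12 (-3.02 ± 0.25), Sox9 (-2.15 ± 0.17), Barx1 (-1.39 ± 0.23) and Lhx8 (-1.52 ± 0.26) fell. Epithelial markers had 0 of 28 measured members higher and 10 lower (0 and 10 over the list alone, set test adjusted p = 0.0061 and 0.33). Muscle genes had 0 of 15 measured members higher and 7 lower (0 and 12 over the list alone, set test adjusted p = 0.0012 and 0.52). The test called 4296 of 14410 genes, 2128 higher and 2168 lower. Median scaling gave 6015, 499 higher and 5516 lower, and moved the median of all genes by -0.36.

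E10 mesenchyme labelled intact culture, against isolated mesenchyme, had more of the early response factors Egr3 (at least 9.82-fold higher, adjusted p = 5.2e-09), Egr2 (3.03 ± 0.24, adjusted p = 1.0e-10) and Fos (2.59 ± 0.20), of Ptch1 (2.10 ± 0.19, adjusted p = 2.6e-09), Axin2 (1.46 ± 0.17), Osr2 (2.39 ± 0.39), Lhx6 (1.34 ± 0.22) and Fgf10 (1.34 ± 0.17). Hedgehog pathway targets had 10 of 16 measured members higher and 2 lower (10 and 2 over the list alone, set test adjusted p = 1.8e-10 and 4.6e-04), Wnt pathway targets 10 of 23 measured members higher and 0 lower (11 and 1 over the list alone, set test adjusted p = 3.7e-07 and 0.0088), and Fgf pathway targets 10 of 22 measured members higher and 0 lower (12 and 0 over the list alone, set test adjusted p = 3.9e-09 and 0.0032). Notch pathway genes had 6 of 13 measured members higher and 2 lower (6 and 3 over the list alone, set test adjusted p = 0.0057 and 0.056). Other cell types moved with the condition: macrophage genes had 0 of 15 measured members higher and 14 lower (0 and 14 over the list alone, set test adjusted p = 1.0e-30 and 0.0011), among them C1qb (-1.95 ± 0.13), and muscle genes 0 of 15 measured members higher and 13 lower (0 and 15 over the list alone, set test adjusted p = 1.6e-10 and 0.18). The test called 1703 of 14410 genes, 652 higher and 1051 lower. Median scaling gave 1536, 303 higher and 1233 lower. The count was 1089 without isolated mesenchyme 3 and 2676 with only the groups compared.

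**Figure D2:**
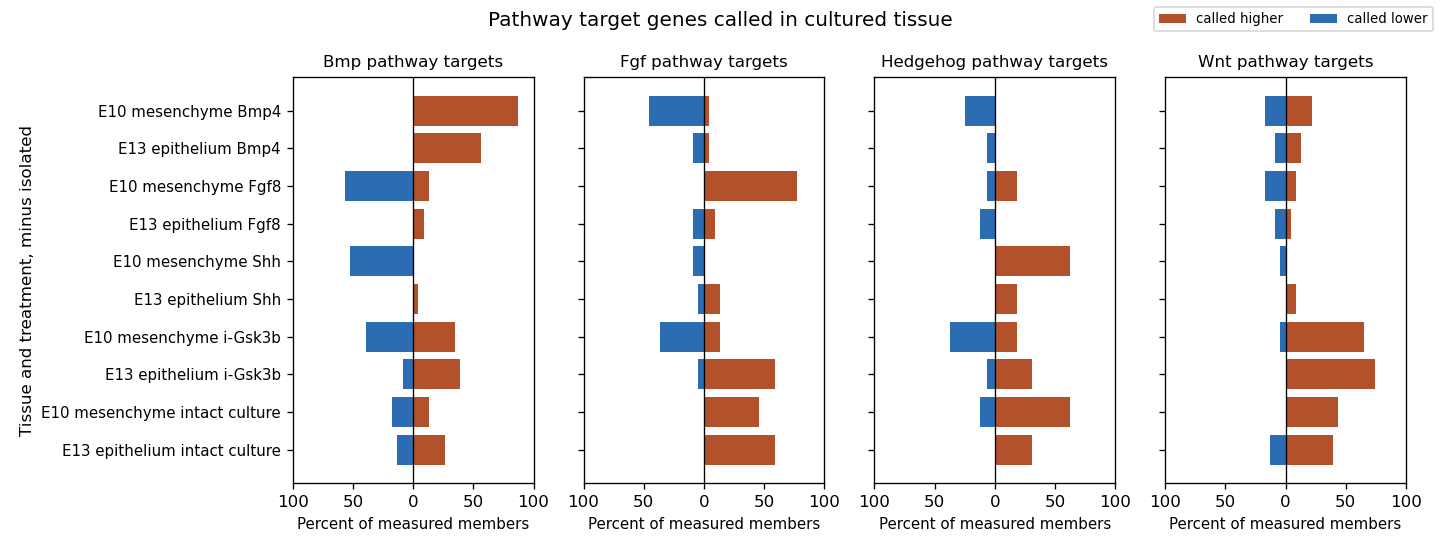
Percent of the measured members of 4 pathway target lists called higher (right of 0) and lower (left of 0) in each cultured comparison with isolated tissue, by limma at an adjusted p under 0.05. In E10 mesenchyme 20 of 23 Bmp targets were higher with Bmp4, 17 of 22 Fgf targets with Fgf8, 10 of 16 Hedgehog targets with Shh and 15 of 23 Wnt targets with i-Gsk3b.

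In E13 epithelium, Bmp4 raised Msx1 (3.05 ± 0.30, adjusted p = 4.4e-08), Dlx2 (2.63 ± 0.27, adjusted p = 6.5e-08), Dlx3 (1.72 ± 0.21), Sostdc1 (2.62 ± 0.26), Nog (at least 3.39-fold higher) and Id1 (1.25 ± 0.15). Shh was higher than in isolated epithelium (1.33 ± 0.34) but not than in the other treatments (-0.055). Bmp pathway targets had 13 of 23 measured members higher and 0 lower (15 and 0 over the list alone, set test adjusted p = 1.9e-12 and 0.0036). Thbs2 (-2.51 ± 0.26, adjusted p = 9.5e-08), the activin subunit Inhbb (at least 3.49-fold lower), Sox2 (-1.13 ± 0.17), Egr1 (-1.42 ± 0.18) and Wnt10b (-0.72 ± 0.15) fell. The endogenous Bmp4 transcript did not pass the test. Limma called 2606 of 14410 genes, 1280 higher and 1326 lower. Median scaling gave 6082, 6009 higher and 73 lower, and moved the median of all genes by 0.44. The spread of the array background was 5.88 intensity units in isolated and 4.51 in intact E13 epithelium, against 9.43 with Bmp4, 9.8 with Fgf8, 11.4 with Shh and 8.78 with i-Gsk3b. A batch therefore cannot be told apart from changes that the treatments share. The count was 1709 without Bmp4 epithelium 3 and 1149 without isolated epithelium 3. With only the groups compared it was 813, and against the mean of the other 3 treatments 1682.

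Against isolated tissue, E13 epithelium with Fgf8 had more of the cornified envelope gene Sprr1a (2.06 ± 0.29, adjusted p = 3.8e-06), Sbsn (1.70 ± 0.30), the haem oxygenase Hmox1 (at least 3.72-fold higher, adjusted p = 2.9e-07) and Notch1 (1.34 ± 0.22). Id1 (0.86 ± 0.15) and Dusp6 (0.61 ± 0.20) were higher too, but lower against the mean of the other 3 treatments (-0.28 and -0.64). Keratinocyte differentiation genes had 10 of 19 measured members higher and 0 lower (12 and 0 over the list alone, set test adjusted p = 2.5e-05 and 0.30). Nme5 (at least 3.6-fold lower, adjusted p = 4.8e-11), Aldoc (-1.58 ± 0.29), Bmp4 (-0.64 ± 0.19), Il17rd (-0.80 ± 0.18) and Egr1 (-0.57 ± 0.18) fell. Fgf pathway targets had 2 of 22 measured members higher and 2 lower (1 and 2 over the list alone, set test adjusted p = 0.74). The spread of the array background was 5.88 intensity units in isolated epithelium, against 9.8 with Fgf8. Isolated arrays that stand apart, or a batch, therefore cannot be told apart from an effect of Fgf8. Limma called 4784 of 14410 genes, 2127 higher and 2657 lower. Median scaling gave 4765, 4128 higher and 637 lower, and moved the median of all genes by 0.27. With only the groups compared the count was 3161.

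Shh in E13 epithelium raised Ptch1 (1.94 ± 0.19, adjusted p = 3.4e-07), the neurotrophin receptor Ntrk2 (1.64 ± 0.29), Sostdc1 (1.12 ± 0.26) and Etv1 (1.14 ± 0.22). The Wnt inhibitor Wif1 (1.56 ± 0.37) and Dusp6 (1.07 ± 0.20) were higher too, but not against the mean of the other 3 treatments (-0.26 and -0.028). Hedgehog pathway targets had 3 of 16 measured members higher and 0 lower (4 and 0 over the list alone, set test adjusted p = 0.0032 and 0.049). Egr1 (-1.15 ± 0.18, adjusted p = 2.7e-04), Jun (-1.13 ± 0.28), the globin Hba-a1 (at least 3.49-fold lower), Wnt10a (-0.56 ± 0.18) and Wnt10b (-0.66 ± 0.15) fell, the last 2 not with median scaling (0.047 and 0.014). The endogenous Shh transcript did not pass the test. Limma called 1632 of 14410 genes, 838 higher and 794 lower. Median scaling gave 6923, 6876 higher and 47 lower, and moved the median of all genes by 0.49. With only the groups compared the count was 254. It was 648 and 972 without Shh epithelium 1 or 2, and 393 without isolated epithelium 3.

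In the same epithelium i-Gsk3b raised Dkk4 (at least 451-fold higher, adjusted p = 1.9e-21), Sp5 (6.87 ± 0.35, adjusted p = 1.3e-15), Notum (at least 53.7-fold higher), Axin2 (3.14 ± 0.17), Shh (4.92 ± 0.34, adjusted p = 1.9e-12), Edar (3.72 ± 0.18), Bmp4 (2.96 ± 0.19), Msx1 (2.89 ± 0.30) and Lmo2 (at least 24.7-fold higher). Wnt pathway targets had 17 of 23 measured members higher and 0 lower (17 and 0 over the list alone, set test adjusted p = 1.7e-17 and 2.6e-04). The Fgf response genes Etv5 (at least 7.27-fold higher), Etv4 (at least 14.4-fold higher), Dusp6 (3.14 ± 0.20) and Etv1 (2.97 ± 0.22) rose too, with 13 of 22 measured members higher and 1 lower (14 and 1 over the list alone, set test adjusted p = 6.9e-11 and 0.0013). Edn2 (at least 14.8-fold lower, adjusted p = 7.2e-19), Anxa8 (at least 9.83-fold lower), Wnt4 (-1.80 ± 0.17), Krt19 (-1.58 ± 0.16) and Wnt7b (-1.52 ± 0.17) fell. Genes of the amino acid and unfolded protein response had 12 of 24 measured members higher and 1 lower (14 and 1 over the list alone, set test adjusted p = 0.0016 and 0.18). Limma called 5085 of 14410 genes, 2321 higher and 2764 lower. Median scaling gave 3911, 2581 higher and 1330 lower, and moved the median of all genes by 0.13.

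Intact culture of E13 epithelium, against isolated epithelium, went with more of Egr2 (3.50 ± 0.24, adjusted p = 1.7e-12), Ccnd1 (2.90 ± 0.17, adjusted p = 1.4e-13), Fgf8 (at least 3.1-fold higher), Barx1 (at least 5.19-fold higher), Shh (1.78 ± 0.34) and the mitotic kinases Aurka (2.47 ± 0.16) and Plk1 (1.99 ± 0.19). Cell cycle genes had 25 of 29 measured members higher and 0 lower (26 and 0 over the list alone, set test adjusted p = 8.2e-21 and 0.017), and Fgf pathway targets 13 of 22 measured members higher and 0 lower (13 and 0 over the list alone, set test adjusted p = 1.7e-07 and 0.0064). Keratins Krt13 (-4.75 ± 0.33, adjusted p = 2.5e-12) and Krt1 (-4.60 ± 0.29, adjusted p = 4.9e-13), Krtdap (-2.88 ± 0.19) and Sprr1a (-2.83 ± 0.29) were lower, and keratinocyte differentiation genes had 0 of 19 measured members higher and 15 lower (0 and 16 over the list alone, set test adjusted p = 1.6e-10 and 0.12). The mesenchymal or cartilage genes Col2a1 (3.02 ± 0.21) and Dcn (2.04 ± 0.28) were higher. Barx1 too is mainly mesenchymal, with a mean log2 level of 11.63 in hand-dissected E13 mesenchyme and 7.23 in epithelium. Whether mesenchyme came along with the intact-culture epithelium was not tested, so these differences and those of the lists may not be epithelial. Limma called 5829 of 14410 genes, 2796 higher and 3033 lower. Median scaling gave 6356, 722 higher and 5634 lower, and moved the median of all genes by -0.32. With only the groups compared the count was 3245.

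Did a signal act differently on the E13 epithelium than on the E10 mesenchyme? Tissue and stage differ together here, and each test used 4 groups with n = 3. For Bmp4, the epithelial effect was above the mesenchymal one for Sostdc1 (3.63 ± 0.37, adjusted p = 4.8e-08), Dlx1 (2.84 ± 0.28) and Krt14 (2.39 ± 0.53) and below it for Gata3 (-3.31 ± 0.24) and Smad6 (-2.14 ± 0.24). For Fgf8 it was above for Id1 (2.07 ± 0.21) and below for Tnc (-3.49 ± 0.44, adjusted p = 9.9e-07), Dusp4 (-2.08 ± 0.27) and Cdkn1a (-2.19 ± 0.27). For Shh it was above for Msx1 (2.19 ± 0.42, adjusted p = 0.0013), Etv1 (2.05 ± 0.32) and Krt14 (2.53 ± 0.53) and below for Pcp4l1 (-2.30 ± 0.34) and Jun (-1.57 ± 0.39). Any of these differences can come in part or whole from the mesenchymal effect. Krt14, an epithelial marker, and Msx1 fell with Shh in E10 mesenchyme, and Id1 fell there with Fgf8. Their differences alone therefore do not show that the signal raised them in epithelium. In epithelium, Id1 with Fgf8 was also lower against the mean of the other treatments. For i-Gsk3b it was above for Etv1 (4.95 ± 0.32, adjusted p = 4.3e-13), Dusp6 (3.73 ± 0.28) and Bmp4 (2.71 ± 0.26) and below for Lum (-5.07 ± 0.66) and Apcdd1 (-3.80 ± 0.26). The Bmp4 effect differed for 2508 of 14410 genes, 1296 higher and 1212 lower. Median scaling gave 5440, 5104 higher and 336 lower, and moved the median of all genes by 0.56. For Fgf8 the count was 3989 of 14410 genes, 2123 higher and 1866 lower. Median scaling gave 7725, 7243 higher and 482 lower, and moved the median of all genes by 0.65. For Shh it was 2107 of 14410 genes, 1072 higher and 1035 lower. Median scaling gave 6005, 5915 higher and 90 lower, and moved the median of all genes by 0.64. For i-Gsk3b it was 4069 of 14410 genes, 1882 higher and 2187 lower. Median scaling gave 5363, 4901 higher and 462 lower, and moved the median of all genes by 0.53. Without isolated epithelium 3 the Bmp4 count was 1636. The Shh count was 1334 without Shh mesenchyme 3, 1330 and 1400 without isolated mesenchyme 1 or 2, 1316 without Shh epithelium 1 and 1041 without isolated epithelium 3.

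Bmp4 and i-Gsk3b shared calls in both tissues. In E10 mesenchyme both raised Msx1, Msx2, Dkk1 and Lef1 and lowered Barx1, Lhx8 and Sfrp2. In all, 567 genes were called in the same direction, 211 higher and 356 lower, against 133 and 136 expected from the counts alone, and 258 in opposite directions. In E13 epithelium both raised Msx1, Dlx1, Dlx2 and Id1. Shh was higher with both than in isolated epithelium, but with Bmp4 not higher than in the other treatments. There 1228 genes were called in the same direction, 584 higher and 644 lower, against 206 and 254 expected, and 155 in opposite directions. Both treatments were compared with the same isolated arrays. The expected counts take no account of this. In simulations without any effect, sharing those arrays alone correlated the 2 sets of differences at r = 0.50, against an observed 0.20 in mesenchyme and 0.38 in epithelium. With effects present r also depends on their size, so these r values are not like for like. The covariance was 0.049 and 0.096, against 0.019 simulated in each tissue. This leaves 0.030 in mesenchyme and 0.077 in epithelium that spread in the shared arrays did not give in these simulations. With the called differences of each treatment placed at random on genes of similar level, 100 simulations with shared arrays gave at most 216 genes in the same direction in mesenchyme and 374 in epithelium, while calling about 1361 and 3313, and 1937 and 4271, genes per treatment. Spread in the shared arrays alone therefore does not give the observed counts, but isolated arrays that stand apart as a group could. The mesenchymal count was 694 (63 higher, 631 lower) with median scaling and 337 without isolated mesenchyme 3. The epithelial count was 1796 (1753 higher, 43 lower) with median scaling and 534 without isolated epithelium 3. With the mean of the other 3 treatments as control, chosen after seeing the data, 599 genes were shared in mesenchyme and 57 in epithelium. Each of the 2 treatments is then part of the other's control, which takes away some of what they share. In epithelium 368 were shared with only the groups compared.

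What changes without Msx1 in each tissue? The Msx1 probe itself did not fall in Msx1 null tissue: in mesenchyme its mean log2 level was 11.43 (SD 0.16) against 11.49 (SD 0.05) in wildtype, n = 3 each, and whether the probe lies in the deleted part is not known. In null epithelium Shh (at least 2.65-fold lower, adjusted p = 1.5e-05), its receptor gene Ptch1 (-1.66 ± 0.24, adjusted p = 1.0e-04) and the early response factor Egr2 (at least 7.65-fold lower, adjusted p = 3.4e-04) fell. Dmkn (-2.57 ± 0.14), Krtdap (-2.02 ± 0.13) and Dsg1a (at least 4.1-fold lower) fell with keratinocyte differentiation genes, which had 0 of 9 measured members higher and 4 lower (1 and 4 over the list alone, set test adjusted p = 1.5e-04 and 0.042). Immediate early and heat shock genes had 0 of 21 measured members higher and 8 lower (0 and 10 over the list alone, set test adjusted p = 6.4e-07 and 0.015). The nuclear receptor Nr2f1 (3.48 ± 0.20, adjusted p = 8.3e-10), Gbx2 (at least 4.64-fold higher), the Notch response factor Hey2 (2.49 ± 0.25), Barx1 (1.65 ± 0.19), Etv5 (2.13 ± 0.18) and Dusp6 (1.07 ± 0.10) rose. Limma called 1738 of 13081 genes, 1009 higher and 729 lower, or 913 in all with median scaling and 256 with only the groups compared. Msx1 wildtype epithelium 1 had a mean correlation of 0.961 with its group, the lowest among these 24 arrays, and without it the count was 1280.

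In Msx1 null mesenchyme the chemokine Cxcl14 (at least 21.6-fold higher, adjusted p = 1.8e-06), Ptx3 (at least 19.5-fold higher), Gbx2 (4.73 ± 0.31), Fgf10 (1.78 ± 0.19), the Wnt antagonist Dkk2 (at least 2.52-fold higher) and Spry2 (1.89 ± 0.12) rose, and Fgf pathway targets had 8 of 22 measured members higher and 1 lower (9 and 2 over the list alone, set test adjusted p = 4.9e-04 and 0.029). Fap (at least 12-fold lower, adjusted p = 2.8e-12), Sall4 (at least 15.6-fold lower), Calca (-3.25 ± 0.30), Sostdc1 (-1.35 ± 0.14), Lef1 (-1.28 ± 0.18), Ptch1 (-1.35 ± 0.24) and Bmp4 (-0.47 ± 0.15, adjusted p = 0.048) fell. Macrophage genes moved with the genotype, with 10 of 10 measured members higher and 0 lower (10 and 0 over the list alone, set test adjusted p = 2.3e-12 and 0.012), among them Mrc1 (2.24 ± 0.14). Cell cycle genes had 1 of 32 measured members higher and 12 lower (1 and 15 over the list alone, set test adjusted p = 2.7e-05 and 0.097). Limma called 1714 of 13081 genes, 973 higher and 741 lower. The effect differed between the tissues for 1316 of 13081 genes, 724 higher and 592 lower in mesenchyme (n = 3 in each of 4 groups), among them Col8a1 (3.98 ± 0.39, adjusted p = 6.0e-07), Tcf7 (-2.69 ± 0.36), Lef1 (-1.48 ± 0.26) and Spry2 (1.47 ± 0.17). With median scaling that count was 868, and with only the groups compared 819.

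Pax9 null epithelium, whose own Pax9 probe was at background in both genotypes, had less Shh (at least 27.3-fold lower, adjusted p = 2.0e-10). Egr3 (at least 4.99-fold lower), Egr2 (at least 7.31-fold lower, adjusted p = 0.0014), Etv5 (-3.04 ± 0.18, adjusted p = 1.8e-09), Lmo2 (at least 5.27-fold lower), Fgf20 (at least 3.05-fold lower), Bmp7 (at least 2.22-fold lower) and Ptch1 (-0.98 ± 0.24) fell as well. Cell cycle genes had 0 of 32 measured members higher and 27 lower (0 and 30 over the list alone, set test adjusted p = 2.3e-25 and 7.9e-04), with Mki67 at -0.84 ± 0.09, and cholesterol synthesis genes 0 of 17 measured members higher and 9 lower (0 and 14 over the list alone, set test adjusted p = 2.2e-11 and 0.0058), with Msmo1 at -1.13 ± 0.16. Nr2f1 (3.98 ± 0.20, adjusted p = 2.0e-10), Chodl (3.60 ± 0.24), Tbx3 (1.52 ± 0.15), Krt15 (1.34 ± 0.21) and Wnt7b (at least 1.99-fold higher) rose. Markers of the other tissue moved with the genotype: mesenchymal markers had 11 of 27 measured members higher and 0 lower (12 and 0 over the list alone, set test adjusted p = 9.2e-09 and 0.04), among them Lum (1.49 ± 0.21) and Col3a1 (1.09 ± 0.10). Limma called 1636 of 13081 genes, 748 higher and 888 lower. Median scaling gave 883, 227 higher and 656 lower. With only the groups compared the count was 2483. It was 1061 without Pax9 wildtype epithelium 3 and 1067 without Pax9 null epithelium 1.

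In Pax9 null mesenchyme the Pax9 probe itself was lower (-1.40 ± 0.14, adjusted p = 3.9e-07), as were Bmp4 (-1.95 ± 0.15, adjusted p = 1.1e-08), Msx1 (-0.68 ± 0.17), Sostdc1 (-2.09 ± 0.14), Ptch1 (-1.27 ± 0.24), Osr2 (-1.10 ± 0.32), Egr3 (at least 19.8-fold lower) and Egr2 (at least 9.09-fold lower). Cell cycle genes had 0 of 32 measured members higher and 22 lower (0 and 23 over the list alone, set test adjusted p = 2.5e-14 and 0.0045). Ptx3 (at least 11.2-fold higher, adjusted p = 2.4e-14), Cxcl14 (at least 10.9-fold higher), Dkk2 (at least 3.72-fold higher) and the bone and cartilage genes Ibsp (at least 6.08-fold higher), Alpl (2.45 ± 0.19), Col2a1 (at least 5.49-fold higher) and Sp7 (1.48 ± 0.16) rose, with 7 of 12 measured members higher and 1 lower (7 and 1 over the list alone, set test adjusted p = 5.6e-07 and 0.0034). Other cell types moved with the genotype: endothelial genes had 12 of 15 measured members higher and 0 lower (12 and 0 over the list alone, set test adjusted p = 7.6e-10 and 0.0069) and macrophage genes 9 of 10 measured members higher and 0 lower (9 and 0 over the list alone, set test adjusted p = 6.3e-13 and 0.0099). Blood cell genes had 6 of 8 measured members higher and 0 lower (6 and 0 over the list alone, set test adjusted p = 8.3e-06 and 0.083). Limma called 2060 of 13081 genes, 1007 higher and 1053 lower. Median scaling gave 1403, 540 higher and 863 lower, and moved the median of all genes by -0.11. The effect differed between the tissues for 1129 of 13081 genes, 603 higher and 526 lower in mesenchyme (n = 3 in each of 4 groups), among them Etv5 (1.76 ± 0.26, adjusted p = 8.5e-05), Msmo1 (1.21 ± 0.22), Lef1 (-1.14 ± 0.26) and Lum (-1.09 ± 0.30). With median scaling that count was 529.

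**Figure D3:**
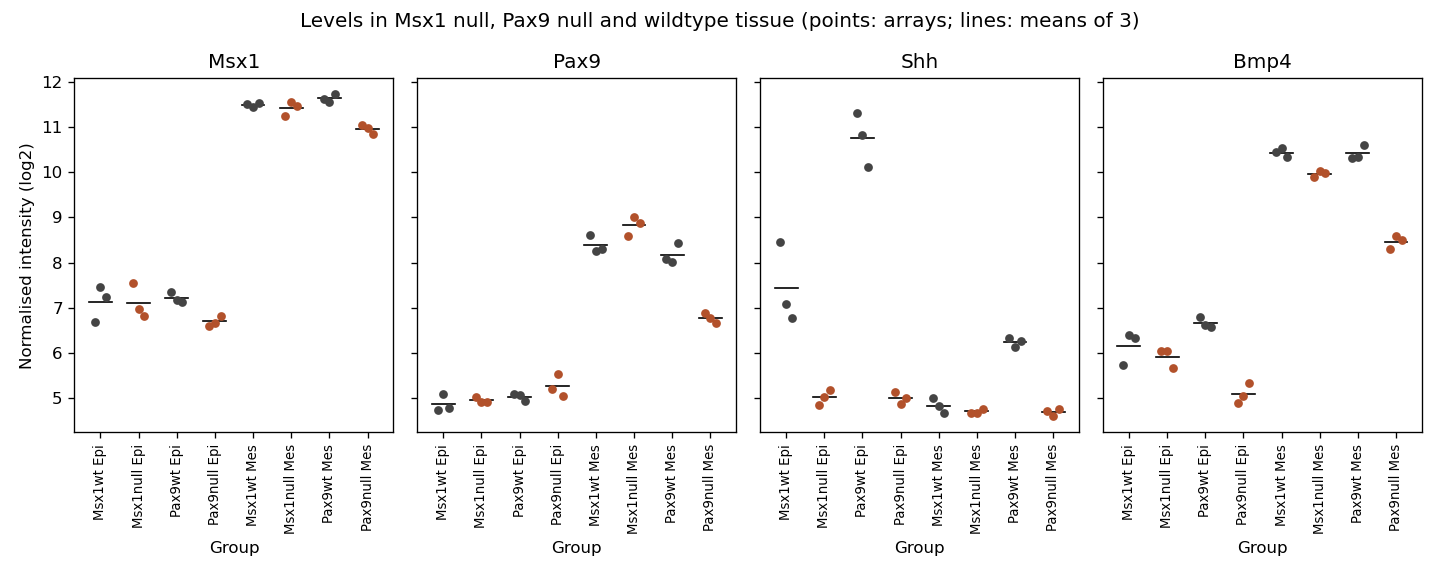
Log2 normalised intensity of Msx1, Pax9, Shh and Bmp4 in each of the 24 arrays of the Msx1 and Pax9 samples, as points, with the mean of each group of 3 as a line. Pax9 null mesenchyme has a mean Bmp4 level of 8.46, against 10.41 in its wildtype.

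Which genes changed in both nulls? In mesenchyme, Cxcl14, Ptx3, Cbln4 and Dkk2 rose and Sall4, Cbln1, Myl4, Fap, Sostdc1 and Bmp4 fell in both nulls. In all, 854 genes were called in the same direction, 466 higher and 388 lower, against 74.9 and 59.6 expected from the counts alone, and 75 in opposite directions. In epithelium, Nr2f1 and Tbx3 rose and Shh, Egr2, Ptch1 and Sostdc1 fell in both nulls; 239 genes were called in the same direction, 160 higher and 79 lower, against 57.7 and 49.5 expected, and 142 in opposite directions, Etv5 and Dusp6 among these. With median scaling the mesenchymal count was 544 (257 higher, 287 lower) and the epithelial count 96 (48 higher, 48 lower), and with only the groups compared the epithelial count was 81. The Pax9 null effect in mesenchyme differed from the Msx1 null effect for 704 of 13081 genes, 313 higher and 391 lower in the Pax9 null (n = 3 in each of 4 groups). Fgf10 (-2.07 ± 0.27, adjusted p = 2.7e-05), Bmp4 (-1.48 ± 0.22, adjusted p = 1.1e-04), Etv5 (-2.11 ± 0.26) and Spry4 (-2.02 ± 0.31) were lower in that comparison, and Sp7 (3.20 ± 0.23, adjusted p = 9.3e-09), Alpl (2.54 ± 0.26) and Calca (3.37 ± 0.42) higher. With median scaling the count was 454 (169 higher, 285 lower).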

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

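In this part, the tests of handling, Fgf response, blood vessels and blood, isolated samples apart, shared isolated arrays, and overall scaling were chosen after the result was seen. Each result listed here is a difference between groups: the effect of a stage, treatment or null differed between tissues, or between nulls, by a test of the difference itself. The stage change from E11.5 to E12.0 differed between laser-captured tissues for 1 gene by limma, Myl4, against 738 genes at an unadjusted p under 0.05. Of 100 splits, the real one included here and below, 17 called as many and the highest other 671. From E12.5 to E13.5 it differed for 481 genes, with 13 of 100 splits as high and a highest other of 5218. Both highest splits exchanged the stages in epithelium alone, which turns the difference into a sum of stage changes, and 32 and 1490 genes changed alike in both tissues. Splits that exchanged most samples of 1 tissue made up 9 of the 16 others as high at E12.0 and 12 of 12 at E13.5, so chance is not excluded for either, and at E13.5 the splits do not speak for it. The count of 481 was 307 without E13.5 epithelium 1 and 303 without E13.5 mesenchyme 3. Of these genes 48 were called in opposite directions in the tissues, among them Hey2 and Sox9. In hand-dissected tissue 6355 genes differed, 749 in opposite directions, with Osr2 and Bmp4 among them, and with 2 arrays per group no splits were counted.

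In culture the effect differed between E13 epithelium and E10 mesenchyme for 2508 genes with Bmp4 (149 opposite, such as Sostdc1), 3989 with Fgf8 (348, such as Htra1, which in epithelium turned to 0.055 against the other treatments), 2107 with Shh (40, such as Etv1) and 4069 with i-Gsk3b (459). Of 100 splits, 1, 2, 1 and 1 were as high for these 4. Exchanging samples within a tissue takes away the effect itself. These splits therefore show an effect in at least 1 tissue, and cannot decide whether it differs between tissues. The highest others were 2096, 4741, 695 and 3309, and the Fgf8 one is above the real count, since exchanging all samples in mesenchyme, with 1 pair in epithelium, again gives nearly a sum. Without isolated E13 epithelium 3 the Bmp4 count was 1636 and the Shh count 1041. The Shh count was also 1334 without Shh mesenchyme 3, 1330 and 1400 without isolated mesenchyme 1 or 2, and 1316 without Shh epithelium 1. The Msx1 null effect differed between tissues for 1316 genes (102 opposite, such as Col8a1) and the Pax9 null effect for 1129 (82, such as Thsd7b). No other split of 100 reached the real count, and the highest others were 1156 and 1011. Both of these exchanged all genotypes in mesenchyme and 1 pair in epithelium, which gives nearly a sum of null effects. The splits thus show a null effect in at least 1 tissue and cannot decide whether it differs between tissues. In mesenchyme the 2 null effects differed for 704 genes (75 opposite, such as Gbx2 and Ibsp), where 5 of 100 splits were as high and the highest other was 1005. That split exchanged all genotypes in the Pax9 line and 1 pair of arrays in the Msx1 line, which adds up null effects that 854 genes share, and all 4 others as high exchanged most of 1 line, so these splits do not exclude chance either.

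For counts between 2 groups of 3 arrays, the 10 splits are too few for a share under 0.05; only the real 1 of 10 reached the real count each time. Real count and highest other were, for laser-captured epithelium minus mesenchyme, 3588 and 0 at E11.5, 3532 and 0 at E12.0, 3992 and 6 at E12.5, 5241 and 1 at E13.0 and 4554 and 0 at E13.5. Between E11.5 and E12.0 they were 100 and 0 in epithelium and 210 and 1 in mesenchyme, and between E12.5 and E13.5 3327 and 0 and 3302 and 0. In E10 mesenchyme they were 1803 and 2 (Bmp4), 6032 and 72 (Fgf8), 230 and 12 (Shh), 4296 and 1 (i-Gsk3b) and 1703 and 1 (intact), and in E13 epithelium 2606 and 7, 4784 and 234, 1632 and 1, 5085 and 574 and 5829 and 833 in the same order. They were 1738 and 6 (Msx1 null epithelium), 1714 and 1 (Msx1 null mesenchyme), 1636 and 2 (Pax9 null epithelium) and 2060 and 5 (Pax9 null mesenchyme). For the shared calls of Bmp4 and i-Gsk3b, 4 of 100 splits were as high in E10 mesenchyme (567, highest other 1204). In E13 epithelium 1 of 100 was (1228, highest other 998). These splits mix treated and isolated arrays and take away the effects, so they cannot decide whether effects are shared. Simulations with shared isolated arrays and effects on random genes gave at most 216 and 374. Isolated arrays that stand apart as a group could still give the observed counts. The 3 higher splits in mesenchyme took the Bmp4 arrays as the control. For the shared calls of the nulls, 1 of 100 splits, the real one, was as high in epithelium (239, highest other 142) and in mesenchyme (854, highest other 1). Mixing genotypes within a line takes away most calls. These splits therefore show that null effects exist and do not test whether the nulls share them.

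Egr2 and Egr3, early response factors, were lower in Pax9 null epithelium and mesenchyme and in Msx1 null epithelium, where Egr3 was at -2.46 ± 0.53. In Msx1 null mesenchyme they did not pass (Egr2 -1.86, adjusted p = 0.063; Egr3 -1.44, adjusted p = 0.082). Longer handling of the wildtype samples would raise other immediate early and heat shock genes there: the 20 others had a median of 0.090 (SE 0.049; 2 called higher, 0 lower) in Pax9 null epithelium and 0.07 (SE 0.11) in mesenchyme, which argues against handling for Pax9. For Msx1 null epithelium that median was -0.47 (SE 0.17; 0 called higher, 7 lower), so handling may account for the change there. In Msx1 null mesenchyme it was 0.019 (SE 0.11; 4 called higher, 3 lower), which gives no sign of handling in that tissue. For a lower Fgf response, the 20 Fgf targets without Egr1 and Fos had a median of 0.043 (SE 0.17) in Msx1 null epithelium with 7 called higher and 0 lower, which gives no sign of it, though the SE leaves a small decrease open. In Pax9 null epithelium the median was 0.011 (SE 0.088) over members called both ways (2 higher, 4 lower), and in mesenchyme -0.016 (SE 0.15; 5 higher, 5 lower), so it cannot be told apart from other causes, and an effect of the genotype itself is untested.

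Mesenchymal markers were higher in Pax9 null epithelium, 11 of 27 measured members with 0 lower, among them Lum and Col3a1. Blood vessels and blood captured with it would raise their markers, and the pooled median of 33 endothelial, blood cell and macrophage genes was 0.022 (SE 0.012). Only 6 of them were above background in either genotype, with a median of 0.45 (SE 0.29) and 1 called higher, so that source stays open. Mesenchyme captured with the null epithelium may contribute: the 200 genes highest in wildtype mesenchyme over epithelium had a median of 0.137 (SE 0.045), with 56 called higher and 20 lower. In the 109 of them above background it was 0.36 (SE 0.13; 46 higher, 16 lower). The 200 were picked with the same wildtype epithelium arrays, and the 109 for a signal in either genotype. Both choices can raise the median by themselves. Epithelial markers had a median of 0.209 in this comparison, or -0.0053 with median scaling, and do not decide it. The median of all 200 lies between the bounds of 0.1 and 0.2 set beforehand, so carry-over cannot be told apart from a change in the epithelium itself, which the design names as genotype and which is untested. Capture of each sample and chip batch are not given.

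Shh in E13 epithelium called 1632 genes, of which 1074 were also called in the same direction with Bmp4 (11 opposite), 1061 with Fgf8 (15) and 831 with i-Gsk3b (52), against 174 in intact culture (612 opposite). The isolated arrays are shared, and simulations with effects on random genes gave at most 118, 201, 225 and 274 in the same direction. Array background would place calls among weak genes, and 20.7% (338) lay in the third of genes with the lowest level. Differences near background are compressed, so few calls may fall there under any cause. This share therefore cannot exclude array background. Overall scaling of the arrays may contribute, since 71.7% (1170) kept their sign with median scaling, though moving all genes alike by its 0.49 would itself leave 85.4% (1394), and which scaling is right is not known. Isolated samples that stand apart from all treated ones stay open: 13.2% (215) stayed called with the same sign against the mean of the other 3 treatments, above the bound of 10%, and a response shared by the added proteins is untested. Background spread differs between the isolated and treated arrays, chip and scan are not given, and the explanation cannot be told apart from a batch.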

How the results depend on the processing

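In this part the control made of the other 3 treatments and the leaving out of each single array were chosen after seeing the data, and the other alternatives before the data were examined. A result is a count of called genes or of shared calls, 42 in all, and its count is taken to hold when an alternative gives one within 1.5 times, whichever genes it is made of. With every probe in place of 1 per gene, 42 of 42 held, 41 without background correction, 40 without a detection filter, 39 each with the authors' values and with replicate number as a block, 29 with only the groups compared in the model and 25 with median scaling. Against the mean of the other 3 treatments, 10 of 14 counts held. For Shh in E13 epithelium, the only one whose calls were followed gene by gene, 13.2% (215 of 1632) stayed called with the same sign. Replicate numbers gave no sign of pairing on average: arrays with the same number in different groups of the cultured table had a mean correlation of residuals of 0.02, against -0.01 for different numbers. Single same-number pairs ranged from -0.27 to 0.40 there, and from -0.61 to 0.61 at E11.5 and E12.0. Arrays that correlated best with their own number were 13 of 36 in culture, 2 of 12 at E11.5 and E12.0, and 13 of 24 in the Msx1 and Pax9 samples. Pairing of some arrays is therefore not excluded. For counts outside 1.5 times the cause was not tested, and those with only the groups compared moved up as well as down. Detected probes, 24.8% to 39.4% per array, limit what can be called, since genes near background count as unchanged.

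With median scaling the counts were 1007 and 1463 for laser-captured epithelium minus mesenchyme at E11.5 and E12.0, 16, 10 and, by limma, 0 for E12.0 minus E11.5 in epithelium, mesenchyme and their difference, and 6082 and 6923 for Bmp4 and Shh in E13 epithelium. They were 5440, 7725 and 6005 for the differences of Bmp4, Fgf8 and Shh effects, 913 and 883 for Msx1 and Pax9 null epithelium, 868 and 529 for the tissue differences of these effects, 454 for Pax9 against Msx1, and 96 and 544 for shared calls of the nulls in epithelium and mesenchyme. With only the groups compared they were 3 and 105 for E12.0 minus E11.5 in epithelium and mesenchyme. For E13 epithelium they were 813 (Bmp4), 3161 (Fgf8), 254 (Shh) and 3245 (intact), and for E10 mesenchyme 385 (Shh) and 2676 (intact). That setting also gave 368 shared calls of Bmp4 and i-Gsk3b in E13 epithelium, 256 and 2483 for Msx1 and Pax9 null epithelium, 819 for the Msx1 tissue difference and 81 shared calls in null epithelium. For E12.0 minus E11.5 in epithelium the count was 64 without a detection filter, 59 with the replicate block and 54 with the authors' values. In mesenchyme it was 114 with the block. The tissue difference over these stages called 2 genes without the filter and, by limma, 0 without background correction, with the block (0) or with the authors' values (0), against 738 at an unadjusted p under 0.05 as reported. The authors' values gave 140 for Shh in E10 mesenchyme. Against the other treatments the counts were 4887 and 3986 for Bmp4 and Shh in E10 mesenchyme, 1682 for Bmp4 in E13 epithelium and 57 for its shared calls with i-Gsk3b. Of 644 list tests 231 were called with the preset correlation and 82 with the estimated one, all 82 among the 231, and medians of 5 lists changed sign with median scaling.

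Counts were also taken without each replicate number and without each array of the groups compared, where a lone remaining array is assumed to vary like the other groups. The lowest and highest for laser-captured epithelium minus mesenchyme were 1973 to 3570 (E11.5), 1925 to 2994 (E12.0), 2615 to 3676 (E12.5), 3568 to 4927 (E13.0) and 2944 to 4138 (E13.5). For E12.0 minus E11.5 they were 0 to 288 in epithelium, 3 to 94 in mesenchyme and 0 to 20 for the difference, and for E13.5 minus E12.5 1285 to 3088, 1499 to 2761 and 81 to 503. Hand-dissected, only single arrays were left out: 4702 to 5094, 4500 to 5168 and 5881 to 5992 between tissues at E10, E11 and E13, 5206 to 6057 and 8032 to 8248 for the stages in epithelium and mesenchyme, and 5388 to 5984 for their difference. In E10 mesenchyme the ranges were 815 to 1501 (Bmp4), 3891 to 6095 (Fgf8), 33 to 225 (Shh), 2194 to 3880 (i-Gsk3b) and 737 to 1473 (intact), in E13 epithelium 611 to 2926, 1982 to 4772, 76 to 2145, 2922 to 4950 and 3380 to 5824, and for differences of effects 835 to 2751, 1593 to 4079, 37 to 2640 and 1606 to 4484, in the same order. Msx1 null ranges were 729 to 2177 in epithelium, 980 to 1660 in mesenchyme and 588 to 1616 for the difference, and Pax9 null ranges 538 to 1233, 1172 to 1846 and 424 to 1065, with 346 to 701 for Pax9 against Msx1. Shared calls ranged over 201 to 531 and 344 to 1452 for Bmp4 and i-Gsk3b in E10 mesenchyme and E13 epithelium, and over 424 to 818 and 65 to 276 for the nulls in mesenchyme and epithelium.

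The text gives 360 gene values or directions, of which 8 reversed under an alternative. In E13 epithelium with Shh, Wnt10a came to 0.047 and Wnt10b to 0.014 with median scaling, which shifts all genes there. Against the other treatments, in the same tissue, Dusp6 (-0.028) and Wif1 (-0.26) with Shh, Dusp6 (-0.64), Id1 (-0.28) and Htra1 (0.055) with Fgf8, and Shh (-0.055) with Bmp4 reversed. That control holds tissue with i-Gsk3b, where Shh and Dusp6 were higher. No gene reversed when a replicate or array was left out, with 3091 values on the same side of the threshold, 221 no longer past it and 4 newly past it. Of the 360 values, 22 kept their direction but no longer passed with median scaling, 16 with only the groups compared, 14 with the authors' values and 13 without a detection filter. Fewer did so without background correction (3), with the block (3) and with every probe (1). Against the other treatments, run only for Bmp4, Fgf8, Shh and i-Gsk3b, it was 13.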

Other observations

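In this part the test of the Pax9 null genes against i-Gsk3b was chosen after the result was seen, and that of the Msx1 null genes before. Tissue labelled EK at E14.5 (3 arrays) has no comparison group, so its levels stand on their own, and levels of different probes are not ranked against each other. Detected in all 3 arrays were Shh (mean log2 level 11.67, SD 0.11), Dusp6 (11.71), the Wnt antagonist Dkk4 (10.55), Lef1 (10.32), Krt14 (10.17), Cdh1 (9.98) and Edar (9.62). So were Wnt10b (8.97), the cell cycle inhibitor Cdkn1a (8.62), Bmp4 (8.48), Wnt10a (8.33), Egr2 (8.12) and Fgf20 (7.67). Fgf8, Fgf4, Pax9 and Runx2 were detected in 0 of 3 arrays. In all 3 arrays, 26 of 30 epithelial markers, 18 of 28 mesenchymal markers, such as Mmp2 (9.02) and Sparc (8.66), and 15 of 25 Wnt targets were detected, against 0 of 17 muscle and 0 of 17 macrophage genes.

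A hypothesis was that genes lost in null epithelium are those that i-Gsk3b raises in E13 epithelium. Of 11110 genes tested in both, 782 were lower in Pax9 null epithelium and 1958 higher with i-Gsk3b, and 248 were both, Shh, Egr2, Egr3, Lmo2, Etv5, Etv1, Gad1 and Bdnf among them. The genes named are among those with the largest changes in the null, and cell cycle genes with smaller changes were among the 248 as well. In a permutation test, random sets matched on mean level gave a median of 141 (95% of sets 121 to 162, p = 1e-04, the smallest that 10000 sets can give). The random sets take no account of genes that change together, as cell cycle genes did in Pax9 null epithelium, so this p-value may be too small. The overlap may reflect a shared set of genes. As the pattern was noticed first, on these data, this stays a hypothesis. Of the other 3 combinations, 87 genes were lower in both, 63 higher in both and 296 higher in the null and lower with i-Gsk3b, against 153, 118 and 131 expected from the counts alone. For the 572 genes lower in Msx1 null epithelium the overlap was 99, against a random median of 99 (82 to 117, permutation p = 0.519), which gives no sign of a shared set in that combination. The other 3 held 165, 171 and 209 genes, against 112, 160 and 177, in the same order. Table and strain differ between the null and cultured samples.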
